A study of Mus musculus and Danio rerio with 33 samples.

How the data were processed

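The values come from the authors' deposited tables of read counts per Ensembl gene, 1 for the mouse organoids and 1 for the zebrafish. Raw reads were not used here. Per the submitters' processing notes, reads were aligned with HISAT2 to GRCm39 (mouse) or GRCz11 (zebrafish), counted with featureCounts and tested with DESeq2, and no versions are given. Per the labels' protocols, the mouse libraries were made with a NEBNext Ultra RNA kit, which does not keep the strand, so genes that overlap on opposite strands share reads. How reads shared by near-identical copies were counted is not given in the sources used here, so the levels of single members of families such as the H2 class I, Reg3, Gsta and Oas genes are uncertain. The zebrafish libraries were made with a stranded total RNA kit with ribosomal RNA depletion.

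All 18 mouse and 15 zebrafish libraries were used and all columns of both tables were assigned. 3 mouse columns carry no replicate number (knock-in untreated, knockout untreated and knockout with TNF), and each was taken as replicate 1 by elimination. The mouse table had gene symbols for 51948 of 56941 IDs, which held 99.9% of the counts. The zebrafish table holds 32520 IDs without names and no zebrafish reference was used here, so 0 of them could be named, and gene lists and the level of birc3 are not analysed here for zebrafish.

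The comparisons, tests, thresholds and alternatives were fixed before the data were examined, apart from those named below as chosen afterwards. Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10), scaled with trimmed mean of M values (TMM) factors, and tested with the edgeR quasi-likelihood test in R 4.3.3, with 1 fit per species over 6 mouse groups or 5 zebrafish groups. A gene is called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison. Values after ± beside a log2 fold change are standard errors, the fold change divided by the square root of the F statistic. Values after ± beside CPM, counts scaled to a common library size, are standard deviations, and CPM are of the total of the tested genes with TMM factors unless another total is named. Alternatives were DESeq2 1.42.0, relative log expression (RLE) factors, no filter, a stricter filter (10 counts in every library of a group and a mean of 1 CPM), a fit on the libraries of a comparison alone, replicate number as a block, and leaving out each library in turn. limma 3.58.1 voom with quality weights and leaving out both doubted libraries (wild type TNF replicate 3 and knockout untreated replicate 3) were chosen after the data were seen. Knockout TNF replicate 3, which also held nerve transcripts (234.7 CPM of the library total, at most 65.1 in the other 16), was not left out there.

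25 lists of mouse genes were written from general knowledge before the count tables were available. They cover NF-kB targets, chemokines and cytokines, mucosal defence, interferon-stimulated genes, antigen presentation, cell death, IAP and TNF receptor complex genes, 7 epithelial cell types (stem, Paneth, goblet, enterocyte, enteroendocrine, tuft and M cells), regenerative and fetal-type genes, cell cycle, stress response, p53 targets, cholesterol synthesis, fatty acid oxidation, the NRF2 oxidative stress response, immune cells, mesenchymal and endothelial cells, mitochondrially encoded genes and immediate early genes. Each list was tested with fry of limma on edgeR's fit, which asks whether its genes move on balance one way and compares it with no other genes, and its p was adjusted over the 25 lists of a comparison. camera with a correlation estimated from the data, and with a preset correlation of 0.01, were the alternatives. A list call that ends with the estimated correlation is given with that adjusted p.

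Genes are named by a fixed rule. It takes Birc3 and its paralogs Birc2 and Xiap. For each comparison it takes the 10 called genes with the largest rise and fall, with a mean of at least 2 log2 CPM, no overlap between the libraries of both groups and no predicted or pseudogene name (5 by smallest p for differences of the TNF response). For each list it takes up to 4 called members in each direction by smallest p. A part of the genes the rule gives is printed, and some are not reported here.

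Whether replicate numbers pair libraries across groups was checked by the Pearson correlation, across genes, of same-numbered libraries after group means were removed, with pairing taken as present where all 3 pairs exceeded 0.1. No mouse comparison met this. It was met for zebrafish heterozygotes against wild type at 3 dpf (0.141 to 0.717) and 8 dpf (0.316 to 0.620) and for homozygotes against heterozygotes at 3 dpf (0.143 to 0.753), and not for homozygotes against wild type, where pair 2 had 0.030.

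Simulated counts with the fitted dispersions and the real library sizes, in which 200 genes were changed, tested the fits. For knockout against wild type organoids, 76% of 100 genes changed by 1 log2 unit and 96% of 100 changed by 2 log2 units were called, with 11 false calls among 183. For the difference of the TNF response in the knockout, 57% and 88% were called, with 4 false calls among 149. For zebrafish homozygotes against wild type, 17% and 60% were called, with 6 false calls among 83. No gene was called in the simulated comparisons without any change.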

Results

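BIRC3 encodes cIAP2, an E3 ubiquitin ligase that joins the TNF receptor complex, where it helps to turn on NF-kB and to hold back cell death. Per the series title, the study concerns BIRC3 variants and Crohn's disease. Small-intestinal organoids of mice with wild type cIAP2, with a heterozygous cIAP2 H312Y knock-in, or with a cIAP2 knockout were grown in ENR medium with or without TNF (10 ng/ml for 15 h), with 3 libraries in each of 6 groups. Zebrafish of a CRISPR/Cas9 birc3 line were profiled as pools at 3 and 8 days post fertilization (dpf), with 3 libraries in each of 5 groups, and there was no homozygous group at 8 dpf. Nothing in the sources used here says that the replicates came from separate animals or cultures, so the p values measure the spread between these libraries, which may be technical.

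Birc3 was measured first in every mouse library. Untreated wild type organoids had 30.6 ± 4.41 CPM (mean and SD, n = 3), knock-in organoids 31.8 ± 1.75 CPM and knockout organoids 17.9 ± 1.87 CPM, which is 58.3% of wild type. With TNF the means were 120.0 ± 12.5, 109 ± 7.14 and 59.6 ± 2.53 CPM, with the knockout at 49.6% of wild type. Each knockout library lay under every wild type library of its treatment (16.2 to 19.9 against 27.2 to 35.6 CPM untreated, and 57.6 to 62.4 against 110.0 to 134 CPM with TNF). The log2 fold change of the knockout against wild type was -0.77 ± 0.12 untreated (adjusted p = 1.5e-04) and -1.01 ± 0.11 with TNF (adjusted p = 6.6e-05), and the knock-in did not differ (0.05 ± 0.11 and -0.14 ± 0.11). TNF raised Birc3 in all 3 genotypes, by 1.97 ± 0.11 in wild type, 1.78 ± 0.11 in knock-in and 1.73 ± 0.12 in knockout organoids. Which part of the gene is deleted is not given in the sources used here, and counts per gene do not separate transcripts of a remaining part from intact transcripts. Birc2 and Xiap, the paralogs that encode cIAP1 and XIAP, were called in no comparison.

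**Figure D1:**
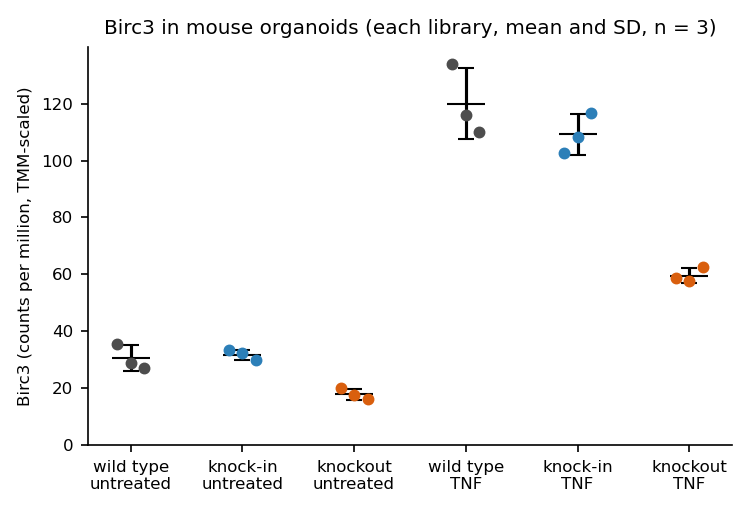
Birc3 in CPM (TMM-scaled) in each of the 18 mouse libraries, with points for libraries and lines for the mean and SD of 3 libraries per group. The knockout libraries sit at 16.2 to 19.9 CPM untreated and 57.6 to 62.4 CPM with TNF, under all wild type and knock-in libraries of the same treatment.

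The mouse libraries held 25.2 to 35.1 M counts, apart from knockout untreated replicate 3 with 8.67 M. Wild type TNF replicate 3 stood apart from all others. It lay at 132.4 on the first principal component (26.8% of variance), where no other library passed 53.4, and 19.9% of its counts were mitochondrially encoded, against 5.54% to 10.1% in the other 17. It also held more transcripts of cells from outside the epithelium than the other libraries, and fewer of tuft and stem cells than the other wild type TNF libraries (list medians -1.16 and -0.60 log2 units). The zebrafish libraries held 14.6 to 25.5 M counts. Their first component (48.4% of variance) separated 3 dpf from 8 dpf. Along the second (22%), the 3 dpf libraries followed the replicate numbers within each genotype, and the homozygotes lay lowest within each number.

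**Figure D2:**
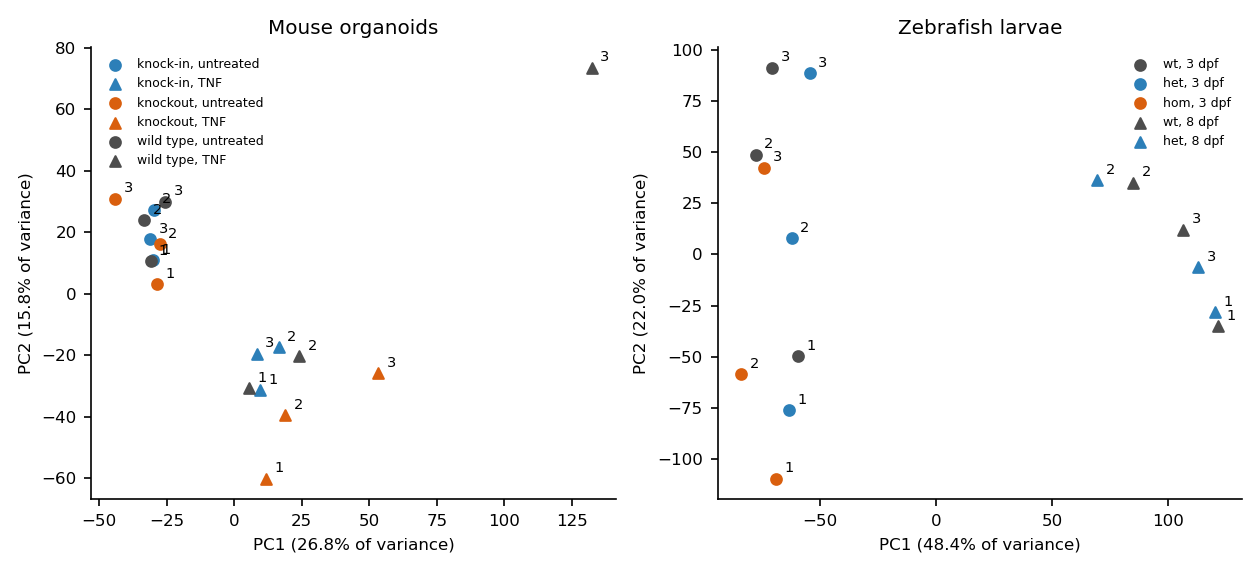
Libraries of mouse organoids (left) and zebrafish larvae (right) on the first and second principal components of log2 CPM, with colour for genotype, shape for treatment or age, and the replicate number beside each point. Wild type TNF replicate 3 lies at 132.4 on the first mouse component, and the zebrafish libraries separate by age on a component with 48.4% of the variance.

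In wild type organoids TNF switched on NF-kB feedback genes, chemokines, antimicrobial genes and antigen presentation. Nfkbia, which encodes the NF-kB inhibitor IkBa, rose by 3.01 ± 0.10 log2 units (adjusted p = 2.2e-13), Tnfaip3, which encodes the ubiquitin-editing enzyme A20, by 2.81 ± 0.12, and Relb, an NF-kB subunit, by 2.54 ± 0.09 (n = 3 libraries per group). Genes near 0 without TNF became abundant. C3, which encodes complement component C3, went from 1.03 ± 0.188 to 320 ± 17.7 CPM, Icam1, an adhesion molecule for leukocytes, from 0.538 to 69.3 CPM, and Ubd, which encodes a ubiquitin-like protein, from 0.022 to 23.7 CPM. Nos2, the inducible nitric oxide synthase, went from 3.31 to 289 ± 57.1 CPM, and Tnf itself from 0.686 to 30.8 ± 6.74 CPM. Among the genes that fell were Lct, which encodes lactase (-2.31 ± 0.27, adjusted p = 8.2e-06), the water channel gene Aqp8 (-1.81 ± 0.21) and the sugar transporter gene Slc5a4b (-2.22 ± 0.14).

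Of the fixed lists, 14 were called in wild type organoids, and 10 of them held with an estimated correlation. Of 29 NF-kB targets 18 rose and 0 fell, 11 were not called, and 22 rose and 1 fell when adjusted over the list alone (median 1.63 log2 units, adjusted p = 5.4e-12 by fry). Of 21 chemokines and cytokines 12 rose and 0 fell (14 and 0 adjusted over the list alone, adjusted p = 4.3e-09), with Cxcl16 at 3.82 ± 0.20 and Ccl20, which attracts lymphocytes and dendritic cells, at 5.19 ± 0.30. Of 20 mucosal defence genes 11 rose and 2 fell (12 and 2 adjusted over the list alone, adjusted p = 4.1e-11), and the Reg3 lectins split, with Reg3g at 5.44 ± 0.17 and Reg3a at -1.30 ± 0.11 (adjusted p = 9.3e-08). Of 25 antigen presentation genes 19 rose and 0 fell (21 and 0 adjusted over the list alone, adjusted p = 3.2e-09), with the class II chaperone gene Cd74 going from 1.13 ± 0.425 to 159 ± 28.7 CPM. Of 32 interferon-stimulated genes 11 rose and 0 fell (15 and 0 adjusted over the list alone, adjusted p = 9.3e-08), with Oasl2 at 3.29 ± 0.21 and Irf7 at 1.98 ± 0.14. Of 12 M cell markers 8 rose and 0 fell (8 and 0 adjusted over the list alone, adjusted p = 2.6e-10), with Spib, a transcription factor that M cells need, at 2.49 ± 0.38. Cell death genes rose (10 of 33 called, 0 fell, 11 and 1 adjusted over the list alone, adjusted p = 1.2e-06), with the pyroptosis effector gene Gsdmd at 1.83 ± 0.10, Fas at 1.94 ± 0.22 and the necroptosis effector gene Mlkl at 1.33 ± 0.16. So did IAP and TNF receptor complex genes (8 of 32 rose, 0 fell, 8 and 0 adjusted over the list alone, adjusted p = 2.6e-07). NRF2 genes rose as well (7 of 20 rose, 0 fell, 10 and 0 adjusted over the list alone, adjusted p = 1.8e-05), with Hmox1 at 1.80 ± 0.21. Stress response genes fell (0 of 25 rose, 5 fell, 0 and 6 adjusted over the list alone, adjusted p = 2.9e-05).

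Other list calls in wild type organoids did not hold with an estimated correlation. They were regenerative genes (5 of 21 rose, 0 fell, 9 and 0 adjusted over the list alone, adjusted p = 0.0032 by fry and adjusted p = 0.177 with an estimated correlation) and cell cycle genes (0 of 28 rose, 5 fell, 0 and 10 adjusted over the list alone, adjusted p = 0.0038 and adjusted p = 0.199 with an estimated correlation). The same held for fatty acid oxidation genes (1 of 20 rose, 4 fell, 3 and 5 adjusted over the list alone, adjusted p = 0.0070 and adjusted p = 0.274 with an estimated correlation) and immediate early genes (3 of 18 rose, 0 fell, 4 and 1 adjusted over the list alone, adjusted p = 0.0022 and adjusted p = 0.207 with an estimated correlation). Stem, Paneth, goblet, enterocyte, enteroendocrine and tuft cell markers were not called as lists by fry (adjusted p from 0.0812 to 0.570), and neither were p53, cholesterol synthesis, immune cell (median 1.29), mesenchymal (median 1.72) or mitochondrially encoded genes. Wild type TNF replicate 3, with its 19.9% mitochondrial share, carried more immune and mesenchymal transcripts than its 2 mates. It carried fewer cell cycle, stem and tuft cell transcripts, so the values of all these lists shift with that library. Its nerve transcripts summed to 360.5 CPM of the library total. The call for cell cycle genes does not rest on it. Without both doubted libraries fry called 15 lists and kept all 14 calls in the same direction. Among enterocyte markers 9 of 30 rose and 4 fell, with Apoa1 at 1.18 ± 0.15 and the fatty acid binding protein gene Fabp1 at -1.11 ± 0.17.

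Over all genes in wild type organoids, edgeR called 977 higher and 423 lower of 16016 tested, 494 of them by at least 2-fold, and the libraries of both groups did not overlap for 23.6% of genes, where 10% is the share by chance. The count depends on single libraries: without wild type untreated replicate 2 it was 864, and leaving out any other gave 977 to 1910. A fit on these 6 libraries alone called 700.

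Knock-in organoids answered TNF with the same main programs. Nfkbia rose by 2.91 ± 0.10 (adjusted p = 5.4e-13), Tnfaip3 by 2.69 ± 0.11 and Relb by 2.47 ± 0.09. C3 went from 0.485 to 299 ± 10.2 CPM, Nos2 from 3.06 to 276 ± 24.1 CPM and Icam1 from 0.478 to 71.5 CPM. Saa3, which encodes an acute-phase serum amyloid, had 0 counts in all 3 untreated libraries and reached 21.9 ± 2.74 CPM. Genes that fell included Fabp1 at -2.01 ± 0.18 (adjusted p = 2.7e-07), the fatty acid transporter gene Cd36 at -2.30 ± 0.20 (adjusted p = 1.7e-07) and Lct at -2.67 ± 0.27 (adjusted p = 1.7e-06). NF-kB targets (18 of 29 rose, 0 fell, 22 and 0 adjusted over the list alone, median 1.59, adjusted p = 6.0e-12), chemokines (9 of 21 rose, 1 fell, 11 and 1 adjusted over the list alone, adjusted p = 2.1e-08) and mucosal defence genes (9 of 20 rose, 2 fell, 13 and 3 adjusted over the list alone, adjusted p = 7.4e-11) rose as lists. Interferon-stimulated genes (9 of 32 rose, 0 fell, 16 and 1 adjusted over the list alone, adjusted p = 3.8e-07) and antigen presentation genes (16 of 25 rose, 1 fell, 18 and 1 adjusted over the list alone, adjusted p = 3.8e-08) rose too, and so did cell death genes (7 of 33 rose, 1 fell, 13 and 3 adjusted over the list alone, adjusted p = 1.2e-05), IAP and TNF receptor complex genes (7 of 32 rose, 0 fell, 8 and 0 adjusted over the list alone, adjusted p = 4.1e-07) and M cell markers (8 of 12 rose, 0 fell, 8 and 0 adjusted over the list alone, adjusted p = 2.4e-10). Fatty acid oxidation genes fell (0 of 20 rose, 8 fell, 0 and 12 adjusted over the list alone, median -0.43, adjusted p = 1.2e-06), and so did stress response genes (0 of 25 rose, 6 fell, 0 and 7 adjusted over the list alone, adjusted p = 3.4e-06). Enterocyte markers also fell by fry (4 of 30 rose, 9 fell, 5 and 12 adjusted over the list alone, adjusted p = 0.0061), with adjusted p = 0.134 with an estimated correlation. Calls for regenerative, cholesterol synthesis, NRF2 and immediate early genes (adjusted p from 0.0250 to 0.0430) had adjusted p from 0.391 to 0.494 with an estimated correlation. Stem cell and p53 lists, which were not called, had a median and a mean of opposite sign. edgeR called 603 genes higher and 354 lower, 392 of them by at least 2-fold. No overlap of libraries was seen for 23.2% of genes (10% by chance).

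In knockout organoids, where Birc3 was lower, TNF again raised the NF-kB program and lowered absorptive and lipid genes. Nfkbia rose by 2.82 ± 0.10 (adjusted p = 7.2e-13), Tnfaip3 by 2.41 ± 0.11 and Relb by 2.09 ± 0.09. Ubd had 0 counts in all 3 untreated libraries and 47.0 ± 15.4 CPM with TNF, Nos2 went from 3.59 to 455 ± 63.9 CPM, Saa3 from 0.041 to 55.2 ± 7.24 CPM and C3 from 1.90 to 418 ± 78.7 CPM. Aqp8 fell by 3.18 ± 0.20, Lct by 3.55 ± 0.28 (adjusted p = 4.6e-08), and Insig1, a sterol sensor gene, by 1.07 ± 0.10 (adjusted p = 3.8e-07). NF-kB targets (20 of 29 rose, 0 fell, 22 and 0 adjusted over the list alone, median 1.37, adjusted p = 3.3e-11), chemokines (10 of 21 rose, 1 fell, 12 and 2 adjusted over the list alone, adjusted p = 4.2e-09) and mucosal defence genes (13 of 20 rose, 3 fell, 14 and 3 adjusted over the list alone, adjusted p = 9.0e-11) rose. Interferon-stimulated genes (12 of 32 rose, 1 fell, 17 and 1 adjusted over the list alone, adjusted p = 2.2e-08) and antigen presentation genes (16 of 25 rose, 2 fell, 20 and 2 adjusted over the list alone, adjusted p = 1.6e-08) rose too, and so did cell death genes (11 of 33 rose, 1 fell, 11 and 3 adjusted over the list alone, adjusted p = 8.0e-06), IAP and TNF receptor complex genes (7 of 32 rose, 0 fell, 8 and 1 adjusted over the list alone, adjusted p = 1.1e-06) and M cell markers (8 of 12 rose, 0 fell, 9 and 0 adjusted over the list alone, adjusted p = 3.9e-11). Enterocyte markers (1 of 30 rose, 13 fell, 1 and 16 adjusted over the list alone, median -0.34, adjusted p = 1.1e-04) and fatty acid oxidation genes (0 of 20 rose, 13 fell, 0 and 15 adjusted over the list alone, median -0.40, adjusted p = 1.7e-07) fell. So did cholesterol synthesis genes (0 of 21 rose, 9 fell, 0 and 12 adjusted over the list alone, adjusted p = 8.0e-06) and stress response genes (0 of 25 rose, 8 fell, 0 and 11 adjusted over the list alone, adjusted p = 1.4e-06). These 4 calls held with an estimated correlation. Regenerative genes rose by fry (adjusted p = 0.0294, adjusted p = 0.446 with an estimated correlation). The immune cell list, which was not called, had a median and a mean of opposite sign. edgeR called 731 genes higher and 738 lower, and 1206 and 804 without a filter on low counts. Knockout TNF replicate 3, which held nerve transcripts (234.7 CPM of the library total), is in this comparison. Libraries were apart for 25.7% of genes (10% by chance).

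Across the 3 genotypes the TNF responses shared a large part. 429 genes were higher and 148 lower in all 3, of 1238 and 1011 called in at least 1 genotype in the same sense, and 7 genes were called in opposite directions in different genotypes. Wild type and knock-in responses shared 520 higher genes (36.8 expected from independent draws) and 173 lower genes (9.35 expected), wild type and knockout 508 (44.6) and 181 (19.5), and knock-in and knockout 474 (27.5) and 298 (16.3). The log2 fold changes of all tested genes had Pearson correlations across genes of 0.511 (wild type and knock-in), 0.618 (wild type and knockout) and 0.548 (knock-in and knockout), and genes are not independent replicates.

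**Figure D3:**
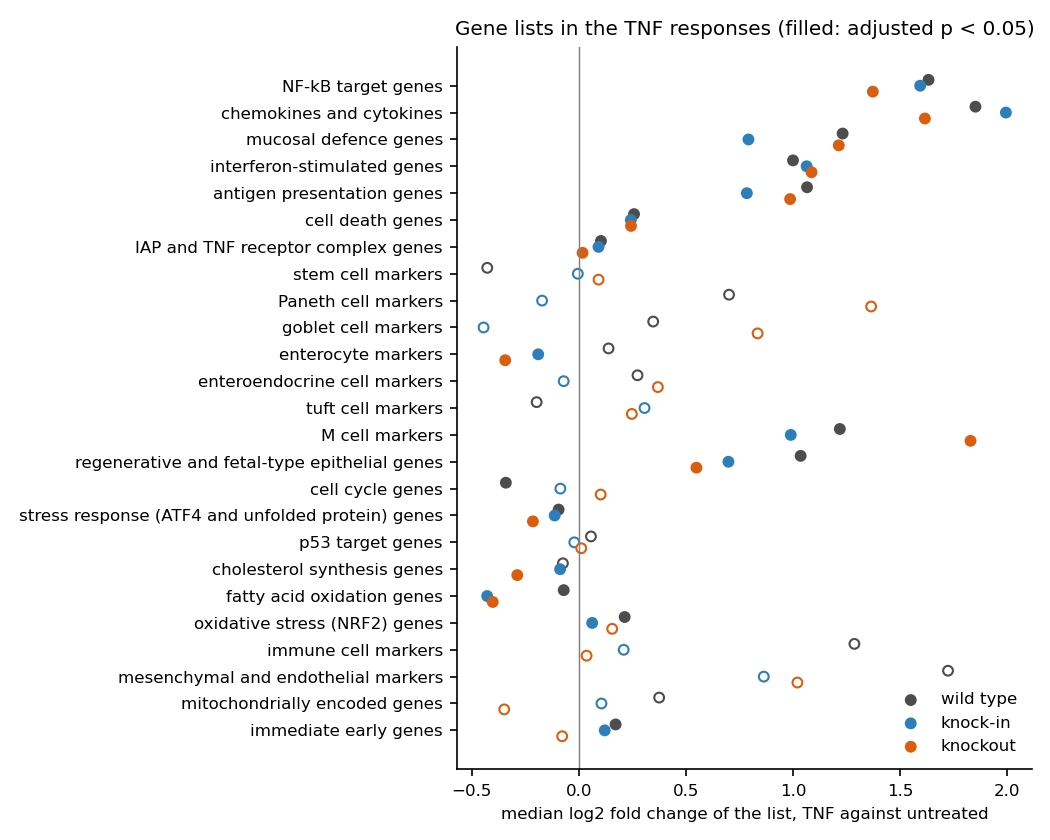
Median log2 fold change, TNF against untreated, of each of 25 fixed gene lists in wild type, knock-in and knockout organoids (n = 3 libraries per group), with filled points where fry gave an adjusted p under 0.05. NF-kB target medians lie at 1.63, 1.59 and 1.37, and fatty acid oxidation genes fall to -0.43 in knock-in and -0.40 in knockout organoids.

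Without TNF, the knock-in hardly differed from wild type. The largest named difference was Cd74, the class II chaperone gene, at 3.90 ± 0.343 CPM against 1.13 ± 0.425 CPM (1.77 ± 0.23 log2 units, n = 3, adjusted p = 0.0027), which lost its call with quality weights (2.05, adjusted p = 0.0569). Cttnbp2nl, a gene of a phosphatase complex, was higher by 0.74 ± 0.12 (adjusted p = 0.0377), and the immediate early gene Egr1 was lower (-0.51 ± 0.09, adjusted p = 0.0490), but both lost their calls whichever of the 6 libraries was left out (Cttnbp2nl with adjusted p from 0.0894 to 0.315, Egr1 with adjusted p from 0.0739 to 0.357). edgeR called 4 genes higher and 2 lower, and the balance turned with DESeq2 (7 higher and 11 lower) and with the replicate block (4 and 5). 375 genes had an unadjusted p under 0.05 of 16016 tested, DESeq2 called 18 in all and limma voom 11, and 9.21% of genes were free of overlap (10% by chance). No list was called by fry (lowest adjusted p = 0.255) or by camera with an estimated correlation, while camera with the preset correlation called 8. Without knock-in replicates 1, 2 or 3 the calls were 2, 3 and 2, and without wild type replicates 1, 2 or 3 they were 3, 2 and 2, and a fit on these 6 libraries alone called 3.

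Untreated knockout organoids, in contrast, had a changed epithelium, with more transcripts of absorptive enterocytes and of fat handling. Akp3, an intestinal alkaline phosphatase gene, was at 241 ± 64.9 CPM against 14.5 ± 1.11 CPM in wild type (4.05 ± 0.21 log2 units, n = 3, adjusted p = 1.6e-09). Pdx1, a transcription factor of the duodenum and pancreas, was at 13.7 ± 2.93 against 0.976 ± 0.326 CPM (3.81 ± 0.37, adjusted p = 1.7e-06). The iron genes Cybrd1, a duodenal iron reductase gene (2.87 ± 0.32), and Slc40a1, which encodes the iron exporter ferroportin (2.49 ± 0.29), were higher as well. Osr2, a transcription factor gene, was lower (-1.57 ± 0.18, adjusted p = 8.5e-06). Cdkn1a, which encodes the cell cycle inhibitor p21, was higher by 1.21 ± 0.10 (adjusted p = 2.2e-07).

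Of 30 enterocyte markers, 28 were higher in the untreated knockout and 0 lower (29 and 0 adjusted over the list alone, median 1.11 log2 units, adjusted p = 4.6e-08 by fry), with the phosphatase gene Alpi at 2.01 ± 0.15, the apolipoprotein gene Apoa4 at 1.98 ± 0.14, the fructose transporter gene Slc2a5 at 1.83 ± 0.12 and the glucose transporter gene Slc5a1 at 1.42 ± 0.11. Of 20 fatty acid oxidation genes 12 were higher and 0 lower (14 and 0 adjusted over the list alone, median 0.65, adjusted p = 1.6e-07), with Creb3l3, a regulator of lipid genes, at 1.17 ± 0.09. Of 20 NRF2 genes 11 were higher and 1 lower (12 and 1 adjusted over the list alone, adjusted p = 1.7e-05). These 3 calls held with an estimated correlation.

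The other list calls for the untreated knockout did not. Cell cycle genes were lower (0 of 28 higher, 19 lower, 0 and 24 adjusted over the list alone, median -0.45, adjusted p = 4.6e-04, and adjusted p = 0.0981 with an estimated correlation), such as the mitotic ubiquitin-conjugating enzyme gene Ube2c at -0.57 ± 0.09. Interferon-stimulated genes (8 of 32 higher, 0 lower, 8 and 0 adjusted over the list alone, adjusted p = 6.1e-05) and antigen presentation genes (9 of 25 higher, 0 lower, 12 and 0 adjusted over the list alone, adjusted p = 3.4e-05) each had adjusted p = 0.0504 with an estimated correlation, with Irf7 at 1.35 ± 0.14 and Cd74 at 2.26 ± 0.23. Chemokines (7 of 21 higher, 0 lower, 9 and 1 adjusted over the list alone, adjusted p = 8.8e-04, and adjusted p = 0.119 with an estimated correlation) included Il18 at 1.31 ± 0.19 and Ccl20 at 1.37 ± 0.31. NF-kB targets were higher by a small margin (6 of 29 higher, 1 lower, 7 and 1 adjusted over the list alone, median 0.17, adjusted p = 0.0335, and adjusted p = 0.589 with an estimated correlation), with Tnfaip3 at 0.58 ± 0.11. p53 targets (6 of 20 higher, 1 lower, 7 and 1 adjusted over the list alone, adjusted p = 2.1e-04, and adjusted p = 0.0955 with an estimated correlation) and cholesterol synthesis genes (7 of 21 higher, 0 lower, 9 and 1 adjusted over the list alone, adjusted p = 3.7e-04, and adjusted p = 0.159 with an estimated correlation) were higher. Stem cell markers were lower (0 of 19 higher, 3 lower, 0 and 8 adjusted over the list alone, adjusted p = 0.0442, and adjusted p = 0.483 with an estimated correlation), with the stem cell genes Olfm4 at -1.13 ± 0.32 and Smoc2 at -0.59 ± 0.12. Cell death genes (6 of 33 higher, 1 lower, 8 and 2 adjusted over the list alone, median 0.07 and mean -0.02, adjusted p = 0.0442) and IAP and TNF receptor complex genes (4 of 32 higher, 2 lower, 5 and 2 adjusted over the list alone, adjusted p = 0.0472) lost the call too, with adjusted p = 0.589 and adjusted p = 0.603 with an estimated correlation. Paneth, goblet and tuft cell lists were not called by fry (adjusted p from 0.815 to 0.992), and the M cell list, also not called, had a median of 0.06 with a test direction of down.

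edgeR called 1484 genes higher and 986 lower in the untreated knockout. Non-overlapping libraries were seen for 33% of genes (10% by chance). Without wild type untreated replicates 2 or 3 the calls were 1577 and 1640. With RLE factors the share of higher calls was 66.8%, against 60.1%.

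**Figure D4:**
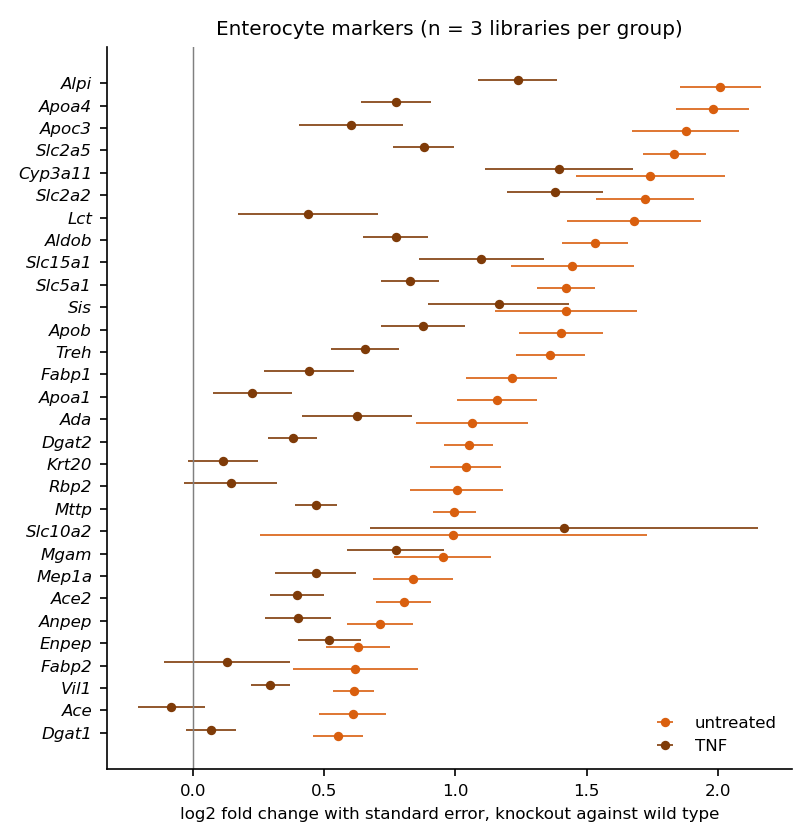
Log2 fold change with standard error of 30 enterocyte markers, knockout against wild type, untreated and with TNF (n = 3 libraries per group). 28 of the markers were called higher untreated and 17 with TNF, and the untreated values run from 0.55 for Dgat1 to 2.01 for Alpi.

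With TNF, knock-in organoids had lower levels of absorptive and lipid genes than wild type organoids. Alpi was lower (-1.12 ± 0.15, adjusted p = 0.0027), as were Akp3 (-1.33 ± 0.21, adjusted p = 0.0051), Fabp1 (-1.09 ± 0.17, adjusted p = 0.0051) and Angptl4, a lipase inhibitor gene (-0.99 ± 0.16). Cdkn1a (-0.67 ± 0.10) and Irf7 (-0.83 ± 0.14) were lower too. Cttnbp2nl was higher (0.88 ± 0.12, adjusted p = 0.0028). Of 30 enterocyte markers 0 were higher and 9 lower (0 and 15 adjusted over the list alone, median -0.31, adjusted p = 0.0024), and of 20 fatty acid oxidation genes 0 were higher and 3 lower (0 and 6 adjusted over the list alone, median -0.24, adjusted p = 0.0018). Both calls held with an estimated correlation. As lists by fry, interferon-stimulated genes (adjusted p = 0.0231), chemokines (adjusted p = 0.0391), stress response genes (adjusted p = 0.0494) and immediate early genes (adjusted p = 0.0089) moved lower on balance. The cell cycle list moved higher on balance (adjusted p = 0.0494). These calls had adjusted p from 0.0976 to 0.268 with an estimated correlation. Without both doubted libraries fry kept 3 of the 7 list calls of this comparison, and with the replicate block 5. Which lists these were is not reported here. Wild type TNF replicate 3 is in this comparison. It had fewer cell cycle, stem and tuft cell transcripts than its mates, and more immune, mesenchymal and mitochondrial ones. Its nerve transcripts summed to 360.5 CPM of the library total. edgeR called 11 genes higher and 140 lower. No overlap of libraries was seen for 17.1% of genes (10% by chance). The count rests on every library: it was 74, 15 and 20 without knock-in TNF replicates 1, 2 or 3, 322, 27 and 86 without wild type TNF replicates 1, 2 or 3, and 1 in a fit on these 6 libraries alone.

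With TNF, knockout organoids kept part of their difference from wild type. Akp3 was higher by 3.73 ± 0.21 (adjusted p = 1.2e-08), Pdx1 by 3.49 ± 0.36 and Slc40a1 by 2.52 ± 0.29, and Reg1, a regenerating islet-derived lectin gene, by 1.87 ± 0.19. Osr2 was lower (-1.90 ± 0.18, adjusted p = 1.7e-05). Saa3 was at 55.2 ± 7.24 against 22.2 ± 4.64 CPM. Of 30 enterocyte markers 17 were higher and 0 lower (22 and 0 adjusted over the list alone, median 0.56, adjusted p = 4.9e-05), with Alpi at 1.24 ± 0.15. Of 32 interferon-stimulated genes 5 were higher and 0 lower (7 and 1 adjusted over the list alone, median 0.60, adjusted p = 7.6e-05), with Parp14 at 0.77 ± 0.12 and Ifit1 at 1.79 ± 0.37. Both calls held with an estimated correlation. As lists by fry, mucosal defence, antigen presentation, p53, fatty acid oxidation and NRF2 genes moved higher on balance (adjusted p from 7.3e-04 to 0.0155). Immediate early genes moved lower (0 of 18 higher, 4 lower, 1 and 5 adjusted over the list alone, adjusted p = 0.0038). These calls had adjusted p from 0.0774 to 0.271 with an estimated correlation. Eda2r, a p53 target and TNF receptor family gene, was higher by 1.67 ± 0.23, and Egr1 lower (-0.89 ± 0.09, adjusted p = 3.5e-05). Wild type TNF replicate 3 is in this comparison too, and the mitochondrial (median -0.85), immune cell (-1.09) and mesenchymal (-1.15) lists, not called by fry, move with it. Nerve transcripts summed to 360.5 CPM of the library total in wild type TNF replicate 3 and to 234.7 CPM in knockout TNF replicate 3. The untreated and TNF comparisons of knockout with wild type shared 226 higher genes (25.4 expected) and 107 lower genes (12 expected). edgeR called 274 genes higher and 198 lower. Libraries were apart for 20.8% of genes (10% by chance). The count was 137 and 143 without knockout TNF replicates 2 or 3 and 1287 (626 higher and 661 lower, so the balance turned) and 174 without wild type TNF replicates 1 or 3, and a fit on these 6 libraries alone called 12.

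Set against the knock-in, the knockout again had higher absorptive, lipid and interferon genes. Untreated, Akp3 was higher by 5.07 ± 0.23, Pdx1 by 4.02 ± 0.38, Alpi by 2.46 ± 0.16 and Reg1 by 3.03 ± 0.20, and Osr2 was lower (-1.95 ± 0.18). Of 30 enterocyte markers 26 were higher and 0 lower (29 and 0 adjusted over the list alone, median 1.12, adjusted p = 7.9e-08), of 20 fatty acid oxidation genes 10 and 0 (13 and 0 adjusted over the list alone, adjusted p = 2.6e-07), and of 32 interferon-stimulated genes 10 and 0 (12 and 0 adjusted over the list alone, adjusted p = 1.1e-05), with Irf7 at 1.34 ± 0.14. These 3 calls held with an estimated correlation. 11 further lists were called by fry and had adjusted p from 0.0885 to 0.473 with an estimated correlation, among them cell cycle genes (0 of 28 higher, 16 lower, 0 and 24 adjusted over the list alone, adjusted p = 4.3e-04, and adjusted p = 0.0885 with an estimated correlation). edgeR called 1197 genes higher and 709 lower. Non-overlapping libraries were seen for 30.4% of genes (10% by chance). Without knock-in untreated replicate 2 the calls were 1244, and without knockout untreated replicate 1 they were 1246.

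With TNF, the knockout again had higher absorptive, interferon and defence genes than the knock-in. Akp3 was higher by 5.07 ± 0.23, Pdx1 by 3.56 ± 0.36, Clca1, a secreted goblet cell protein gene, by 2.64 ± 0.65 and Zg16, a goblet cell lectin gene, by 2.48 ± 0.58. Enterocyte markers (24 of 30 higher, 0 lower, 27 and 0 adjusted over the list alone, median 0.97, adjusted p = 3.3e-07), interferon-stimulated genes (8 of 32 higher, 0 lower, 9 and 0 adjusted over the list alone, median 0.99, adjusted p = 8.6e-07), fatty acid oxidation genes (9 of 20 higher, 0 lower, 14 and 0 adjusted over the list alone, adjusted p = 2.3e-06), mucosal defence genes (5 of 20 higher, 0 lower, 7 and 0 adjusted over the list alone, adjusted p = 7.6e-05), antigen presentation genes (7 of 25 higher, 0 lower, 9 and 0 adjusted over the list alone, adjusted p = 1.2e-04) and p53 targets (5 of 20 higher, 0 lower, 5 and 0 adjusted over the list alone, adjusted p = 1.5e-04) were higher. These calls held with an estimated correlation. 6 further lists were called by fry, with adjusted p from 0.0760 to 0.436 with an estimated correlation. edgeR called 802 genes higher and 414 lower. Knockout TNF replicate 3 with its nerve transcripts (234.7 CPM of the library total) is in this comparison. No overlap of libraries was seen for 31.4% of genes (10% by chance). Without knock-in TNF replicates 2 or 3 the calls were 646 and 657, and without knockout TNF replicate 2 they were 737.

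The next comparison asks whether a genotype changes the TNF response itself. In the knockout, most genes called with a changed response rose less or fell more with TNF than in wild type. Creb3l3 differed by -0.88 ± 0.13 log2 units (adjusted p = 0.0064), the stearoyl-CoA desaturase gene Scd1 by -1.19 ± 0.16 (adjusted p = 0.0053), the retinol saturase gene Retsat by -0.88 ± 0.11 (adjusted p = 0.0042) and Cdkn1a by -0.99 ± 0.14 (adjusted p = 0.0064). Cd74 also rose less (-1.72 ± 0.28, adjusted p = 0.0065), from a higher untreated level in the knockout (5.38 ± 0.722 CPM of Cd74 against 1.13 ± 0.425 CPM in wild type). The response of Birc3 did not differ (-0.24 ± 0.16), nor did that of the NF-kB list (median -0.04, adjusted p = 0.497). Enterocyte markers had a lower response (0 of 30 higher, 8 lower, 0 and 19 adjusted over the list alone, median -0.53, adjusted p = 8.1e-04), and so had fatty acid oxidation genes (0 of 20 higher, 3 lower, 0 and 6 adjusted over the list alone, median -0.34, adjusted p = 8.1e-04). Both calls held with an estimated correlation. 6 further lists were called by fry and had adjusted p from 0.0974 to 0.146 with an estimated correlation. On balance over the list, the response was lower for chemokines, cholesterol synthesis, NRF2 and immediate early genes. It was higher for stem cell and cell cycle genes, for which wild type TNF replicate 3 was low. These calls by fry do not rest on that library. Without both doubted libraries fry called 9 lists and kept all 8 calls of this comparison in the same direction. Wild type TNF replicate 3, with more immune, mesenchymal and mitochondrial transcripts than its mates, is in this comparison. Knockout TNF replicate 3 is in it too. Nerve transcripts summed to 234.7 CPM of the library total there and to 360.5 CPM in wild type TNF replicate 3. edgeR called 2 genes with a higher and 152 with a lower response, of 16016, and limma voom 100 and 609. The count was 90 and 63 without knockout untreated replicates 1 or 2, 84 and 70 without knockout TNF replicates 1 or 3, 66 and 48 without wild type untreated replicates 1 or 2, 299 and 49 without wild type TNF replicates 1 or 2, and 17 in a fit on these 12 libraries alone.

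In the knock-in, edgeR called no gene with a changed TNF response. 831 of 16016 genes had an unadjusted p under 0.05, DESeq2 called 58 and limma voom 91, and without wild type untreated replicate 1 or wild type TNF replicate 1 edgeR called 1. The enterocyte list had a lower response (median -0.36, 0 higher and 14 lower adjusted over the list alone, adjusted p = 0.0136), and so had the fatty acid oxidation list (median -0.25, 0 higher and 5 lower adjusted over the list alone, adjusted p = 0.0136). Both calls held with an estimated correlation. Antigen presentation genes (median -0.21, adjusted p = 0.0421, and adjusted p = 0.0863 with an estimated correlation) and NRF2 genes (median -0.23, adjusted p = 0.0421, and adjusted p = 0.0554 with an estimated correlation) did not hold.

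Comparisons against the same wild type libraries are not independent. Untreated, 4 genes were called in the same direction for the knock-in and the knockout (2 higher, 0.371 expected, and 2 lower, 0.123 expected), and the covariance of both fold changes was 0.173 against 0.115 simulated. Their Pearson correlation across genes was lower than simulated (0.406 against 0.485). With TNF, 10 genes were shared (2 higher, 0.188 expected, and 8 lower, 1.73 expected), with a covariance of 0.271 against 0.141 and a Pearson correlation across genes of 0.464 against 0.506. With 3 wild type libraries the controls cannot be split between the comparisons, so part of any excess may come from the shared libraries.

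In zebrafish, birc3 homozygotes at 3 dpf differed from wild type in 232 of 20641 genes. 180 genes were higher in homozygotes and 52 lower, and 212 of them differed by at least 2-fold. These counts are from the fit that leaves replicate number out. With replicate number as a block, edgeR called 3661 genes, and the excess of higher genes turned (1685 higher and 1976 lower). Same-numbered libraries had correlations of 0.631, 0.030 and 0.671, so the rule for pairing was not met, but pairs 1 and 3 were alike. ENSDARG00000079105 was at 63.1 ± 16.2 against 1.02 ± 0.808 CPM (5.96 ± 0.99 log2 units, n = 3, adjusted p = 0.0086) and ENSDARG00000100900 at 97.4 ± 26.3 against 2.81 ± 3.78 CPM. ENSDARG00000093608 was at 0.240 ± 0.17 against 3.63 ± 0.892 CPM (-4.01 ± 0.55, adjusted p = 0.0024) and ENSDARG00000020602 at 2.30 ± 1.28 against 30.9 ± 13.9 CPM (-3.71 ± 0.57). The libraries did not overlap for 13.8% of genes (10% by chance). That 10% holds for libraries without a structure by number. In the zebrafish comparisons, where libraries of a number were alike, the share without an effect may differ from it. Heterozygotes against wild type at 3 dpf, with no gene called, had 4.20%. The edgeR count was 113, 95 and 132 without wild type replicates 1, 2 or 3 and 100 and 96 without homozygote replicates 1 or 2, and a fit on these 6 libraries alone called 98.

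Against heterozygotes, homozygotes had 234 genes higher and 78 lower at 3 dpf. Libraries were apart for 14.1% of genes (10% by chance). 158 of the higher and 45 of the lower genes were also called against wild type (2.04 and 0.197 expected), in comparisons that share the homozygote libraries. With replicate number as a block, edgeR called 2411 in place of 312, and the excess of higher genes was gone (1234 higher and 1177 lower). The count was 184 and 130 without homozygote replicates 1 or 2 and 134 and 129 without heterozygote replicates 2 or 3, and a fit on these 6 libraries alone called 154.

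Heterozygotes did not differ detectably from wild type at either age. At 3 dpf edgeR, DESeq2 and limma voom each called 0 genes, and 175 genes had an unadjusted p under 0.05. 4.20% were free of overlap (10% by chance for libraries without a structure by number). At 8 dpf all 3 tools called 0 genes, 143 had an unadjusted p under 0.05, and 3.56% were free of overlap. In simulated counts without pairing, the homozygote comparison, with the same number of libraries, called 17% of genes changed by 1 log2 unit and 60% of those changed by 2 units, so a difference of that size in single genes could be missed. With the replicate number as a block, by which these libraries pair, edgeR also called 0 genes at both ages. The covariance of the fold changes of heterozygotes and homozygotes against the shared wild type libraries was 0.0886 against 0.149 simulated, with a Pearson correlation across genes of 0.232 against 0.489. The simulated libraries were drawn without pairing by number, so these simulated values do not show what paired libraries give without an effect.

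Age separated the zebrafish libraries far more than genotype. Between 3 and 8 dpf, 3184 genes rose and 3767 fell in wild type larvae and 2853 rose and 3505 fell in heterozygotes. Which direction held more genes depends on the scaling, since with RLE factors 3579 rose and 3282 fell in wild type and 3119 rose and 3064 fell in heterozygotes. 2492 genes rose in both (440.1 expected) and 3088 fell in both (639.7 expected). 46.4% and 42.1% of genes were free of overlap (10% by chance). The age effect differed between heterozygotes and wild type in 0 genes by edgeR, DESeq2 and limma voom, with 161 genes at an unadjusted p under 0.05.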

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

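The tests for cells from outside the epithelium, material of the other sex, mitochondrial transcripts, low depth and shared numbers below were chosen after the result was seen, and the idea of nerve tissue came from seeing Meg3, Snap25 and Apoe high in a library. A gene or list is taken up here because its TNF response differed between a mutant genotype and wild type in a test of that difference.

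In the knockout, 154 genes had a response that differed from wild type. The genes with the smallest p were Marcksl1 (0.65 log2 units) and Ifitm3 (0.82) with a higher response, and Retsat (-0.88), Scd1 (-1.19), Cdkn1a (-0.99), Cyp2d26 (-0.96) and Creb3l3 (-0.88) with a lower response. List medians of the difference were -0.30 for chemokines and cytokines, 0.51 for stem cell markers, -0.53 for enterocyte markers, 0.40 for cell cycle genes, -0.22 for cholesterol synthesis, -0.34 for fatty acid oxidation, -0.32 for NRF2 and -0.33 for immediate early genes. In the knock-in, where no gene was called by edgeR, 831 genes had an unadjusted p under 0.05 and DESeq2 called 58, the medians were -0.21 for antigen presentation, -0.36 for enterocyte markers, -0.25 for fatty acid oxidation and -0.23 for NRF2 genes. With an estimated correlation, only the enterocyte and fatty acid oxidation lists held, in both genotypes.

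Whether chance grouped the libraries this way is not settled for the 154 genes of the knockout, and no split tested the lists. The real grouping was set beside a random draw of the exchanges of libraries between genotypes within each treatment. Of these 33 splits, 2 gave as many genes, the real one included, and the other one called 971. That split puts wild type TNF replicates 1 and 3 with knockout TNF replicate 3 and leaves the untreated libraries in place. Its contrast thus still holds the genotype difference without TNF, for which 2470 genes were called. Exchanges within a treatment therefore do not show what libraries without a genotype effect would give, and this count of splits decides nothing. For the knock-in, with 0 genes called by edgeR, 33 of 33 splits drawn in this way had to give as many, so this tests nothing. The highest of those drawn called 32.

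Wild type TNF replicate 3 stood apart from all other mouse libraries. A larger mitochondrial share alone is argued against, since without mitochondrially encoded genes the SD over genes of its log2 difference from its group mates was still 1.27, where no other library passed 0.853 against its own mates. Transcripts from outside the epithelium may be part of it, since the lower of the immune and mesenchymal list medians was 1.86 log2 units above its mates, with summed levels of 26.1 CPM for 13 immune markers (6.52 in its mates, at most 13.3 in the other 17 libraries) and 32.2 CPM for 6 mesenchymal and endothelial markers (11.4 and 16.3). Material of the other sex stays open: the Y-linked sum was 93.9 CPM of the library total, under the 107.8 to 186.4 of the other 17, but 117.1 CPM of the counts that are not mitochondrially encoded, where the lowest other was 115.8, while Xist was at 19.1 CPM against at most 4.18. Nerve tissue stays open. 20 nerve genes (5 of them over 1 CPM in organoids) summed to 360.5 CPM of the library total, with 234.7 CPM in knockout TNF replicate 3. That is 6.77 times the median of the others and short of the ratio set for it. The sum in the others rests in part on Slc1a3 and Camk2b (medians of 28.5 and 13.5 CPM in the other 16), which lowers the ratio. 16 of the 20 genes were highest in wild type TNF replicate 3. No biological explanation was tested.

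Untreated knockout organoids had higher enterocyte genes than wild type. Low depth of knockout untreated replicate 3 is argued against, since without it 28 of the 28 markers were still called higher. A more proximal piece of intestine stays open. The median of 4 distal enterocyte markers was 1.11 log2 units, where a proximal shift would lower them. That median rests on few genes and cannot decide this. Slc51a (1.00 ± 0.17) and Slc51b (1.23 ± 0.24) were called higher, Amn was unmoved (0.05 ± 0.15), Cubn was near the floor and Fabp6 was not tested. Of 4 proximal markers, 3 were called higher and 0 lower. A greater maturity of enterocytes along the whole axis is consistent with that same value of 1.11 beside 1.14 for 4 proximal markers (Gata4 not called, 0.18 ± 0.12), but with TNF these medians parted (0.12 and 0.49), while the enterocyte list stood at 0.56. The rise of Pdx1 and fall of Osr2 leave a difference in the region of origin open, and the genotype itself, which is confounded with the line of organoids, was not tested apart from it.

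Zebrafish homozygotes differed from wild type at 3 dpf. With the number as a block 3661 genes were called (1685 higher and 1976 lower), all 232 among them, but each number holds 1 library of each genotype, so a clutch or batch shared by number is balanced between the genotypes and this decides nothing. A difference in developmental stage stays open. The fold changes of the 232 genes had a Pearson correlation across genes of 0.111 with those from 3 to 8 dpf in heterozygotes. These share no library with them. Over all tested genes the correlation was 0.133. The value of 0.111 lies between those set in advance for and against a stage difference, so it does not decide this. 138 of the 180 higher genes were higher at 8 dpf but 15 of the 52 lower genes lower. Without names for the genes no biological explanation was tested.

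For comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. In each of the following, 1 of the 10, the real one, gave a count as large: the TNF responses of wild type (1400, highest other 2), knock-in (957, highest other 0) and knockout (1469, highest other 0), the knock-in against wild type untreated (6, highest other 0) and with TNF (151, highest other 0), the knockout against wild type untreated (2470, highest other 0) and with TNF (472, highest other 58), the knockout against the knock-in untreated (1906, highest other 0) and with TNF (1216, highest other 0), zebrafish homozygotes against wild type (232, highest other 0), and 8 against 3 dpf in wild type (6951, highest other 0) and heterozygotes (6358, highest other 0). For homozygotes against heterozygotes, with 312 genes, 2 of 10 splits gave as many and the other called 1141. It exchanges heterozygote replicate 1 with homozygote replicate 3, so that both number 1 libraries lie on one side and both number 3 libraries on the other. The real split parts all 3 pairs of numbers, this one parts 1, and the remaining 8, with every other split that parts all 3, called fewer than 312. This points to a structure of the samples by number, and with the number as a block 2411 genes were called. Heterozygotes against wild type gave 0 genes by edgeR, so that 10 of 10 splits had to give as many at both ages (highest other 0), with 175 genes at 3 dpf and 143 at 8 dpf at an unadjusted p under 0.05 and 0 by DESeq2. For the difference of the age effect, edgeR and DESeq2 also called 0 genes (161 at an unadjusted p under 0.05). Its splits were the real grouping and a random draw of exchanges, and 33 of 33 had to give as many too. The highest of those drawn called 4213, which points to the same structure.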

How the results depend on the processing

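Tests with quality weights and without both doubted libraries were chosen after the results were seen. Of 687 pairs of a named gene and a comparison, 687 were still called with DESeq2, 676 with RLE factors, 683 with the block, 678 with quality weights and 614 without both doubted libraries, and 3432 of 4260 when each library was left out in turn, and none was called in the other direction under these alternatives. The other alternatives were not run for named genes. Counts of called genes moved by over 1.5 times as follows. Where fewer genes or libraries enter, the alternative's own construction is part of the reason, and otherwise the cause was not tested.

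With DESeq2 the counts rose to 18 (knock-in against wild type untreated), 434 (knock-in against wild type, TNF), 1354 (knockout against wild type, TNF), 1825 (knockout against knock-in, TNF), 58 and 540 (difference of the TNF response in knock-in and knockout), 511 (homozygotes against wild type) and 644 (homozygotes against heterozygotes). Genes shared by the comparisons with the same wild type libraries were 8 untreated (4 by edgeR) and 36 with TNF (10 by edgeR).

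Without a filter on low counts they were 2257 (TNF response, wild type), 49 (knock-in against wild type untreated, 22 higher and 27 lower), 964 and 1521 (knock-in and knockout against wild type, TNF), and 190 and 496 (difference of the TNF response in knock-in and knockout). With the stricter filter the last was 251. Genes with a higher response in the knockout were 2 of the 154 reported, and 149 of 496 without a filter, 156 of 600 with the block within genotype, 100 of 709 with quality weights and 52 of 540 with DESeq2.

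Fitted on the libraries of the comparison alone they were 700 (TNF response, wild type), 3 and 1 (knock-in against wild type untreated and with TNF), 12 (knockout against wild type, TNF), 17 (difference of the TNF response in the knockout), 98 and 154 (homozygotes against wild type and heterozygotes).

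With replicate number as a block they were 1106 (knockout against wild type, TNF, nearly even at 567 higher and 539 lower), 364 (difference of the TNF response in the knockout), 3661 and 2411 (homozygotes against wild type and heterozygotes, where the majority of higher genes was lost, with 1685 and 1234 higher and 1976 and 1177 lower) and 9667 (8 against 3 dpf, heterozygotes). With the block within genotype they were 2134 (TNF response, wild type) and 600 (difference of the TNF response in the knockout).

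With quality weights, where wild type TNF replicate 3 had the lowest weight of the mouse libraries (0.164), they were 2866, 1628 and 2581 (TNF responses of wild type, knock-in and knockout), 11 and 4392 (knock-in and knockout against wild type untreated), 616 and 2521 (the same with TNF), 3185 and 3867 (knockout against knock-in untreated and with TNF), 91 and 709 (difference of the TNF response in knock-in and knockout), 2410 and 1578 (homozygotes against wild type and heterozygotes) and 10522 and 10090 (8 against 3 dpf, wild type and heterozygotes). Without both doubted libraries they were 85 and 196 (knock-in and knockout against wild type, TNF).

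Leaving out 1 library at a time gave 864 to 1910 (TNF response, wild type), 2 to 3 and 1577 to 1966 (knock-in and knockout against wild type untreated), 15 to 322 and 137 to 1287 (the same with TNF), 1244 to 1507 and 646 to 1251 (knockout against knock-in untreated and with TNF), 0 to 1 and 48 to 299 (difference of the TNF response in knock-in and knockout), and 95 to 234 and 129 to 310 (homozygotes against wild type and heterozygotes). For 8 against 3 dpf the majority turned from lower to higher genes with RLE factors (3579 higher and 3282 lower in wild type, 3119 and 3064 in heterozygotes) and with DESeq2 (4101 and 3781, 3677 and 3554). When libraries were left out, the other comparisons stayed within 1.5 times of their count.

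Of 275 list tests, fry called 108. camera with an estimated correlation called 52, all among the 108, and with the preset correlation 134, of which 96 were. fry with the block called 115 (103 shared), with RLE factors 114 (106 shared) and without both doubted libraries 114 (101 shared).

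What depth limits was not tested apart from the number of libraries. Without knockout untreated replicate 3, which held 8.67 M counts, 1806 genes were called for knockout against wild type untreated, 1725 of them among the 2470, and without replicate 2, which held 32.9 M, 1733 were called.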

Other observations

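The knockout differed from the other genotypes in several genes not described above, most of them in no list. Without TNF, Otop3, a proton channel gene, was higher than in wild type by 2.55 ± 0.26 log2 units and Paqr9 by 2.46 ± 0.31. Of the Paneth cell list, Pnliprp2, a pancreatic lipase-related gene, was higher by 2.17 ± 0.30. Zfp503, a zinc finger gene, was lower (-1.31 ± 0.16), as was Tifa, which carries signals from bacterial sugars to NF-kB (-1.39 ± 0.27).

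TNF also moved the following genes in all 3 genotypes. Guca2a, which encodes the gut hormone guanylin, went from 37.5 to 432 CPM in wild type, from 50.2 to 337 in knock-in and from 37.1 to 456 in knockout organoids. Adgrd1, an adhesion receptor gene, went from 9.84 to 125 CPM, from 6.86 to 94.9 and from 38.2 to 185. Cyba, a subunit gene of NADPH oxidases, rose by 3.45 ± 0.13, 3.32 ± 0.13 and 3.83 ± 0.13. Reg3a fell in all 3 (-1.30 ± 0.11, -1.69 ± 0.11 and -2.17 ± 0.11) while Reg3g rose (5.44 ± 0.17, 4.95 ± 0.16 and 5.59 ± 0.17). Gpx3 had 55.4 ± 76.4 CPM in knockout organoids with TNF, so 1 library holds most of it.

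A test fixed before its result was seen asked whether untreated knockout organoids hold a part of the TNF program without added TNF. To avoid shared libraries, genes called higher in the knockout against the knock-in, untreated, were set against genes that TNF raised in wild type. 314 were in both, where 73.0 would be by independent draws, a ratio of 4.30, and 101 genes were lower in the knockout and lowered by TNF (18.7 by independent draws). Of opposite directions, 24 genes were lower in the knockout and raised by TNF (43.3 by independent draws), and 69 were higher in the knockout and lowered by TNF (31.6 by independent draws), which such a state does not account for. Genes are not independent draws. The overlaps in the same direction may reflect an inflammatory state without added TNF. But the overlap of genes higher in the knockout and lowered by TNF also had a ratio of 2.18, so the ratio of 4.30 does not by itself show such a state. Whether such a state would follow from the genotype or from the culture of that line was not tested.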
